A study of Mus musculus with 43 samples.

How the data were processed

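The deposited data are 43 RNA sequencing libraries from mouse visual cortex, in 9 groups. Neuronal nuclei were sorted by NeuN and sequenced with a total RNA kit for low input, and microglia were sorted by CD11b and CD45 and sequenced with a full-length cDNA kit, per the labels' protocols. Each library has its own file of FPKM values (fragments scaled to transcript length and to the total of mapped fragments) for 23953 gene symbols, as deposited by the authors. STAR, Cufflinks 2.0.0 and the mouse genome build mm9 are named in the submitters' processing notes, with no role or order. The strand setting, the gene annotation and any filter are not given in the sources used here. The reference genome at hand is of another build, so no coordinates are given. Genes are named by the symbols in the files.

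FPKM values are not counts, and the depth of each library is unknown. No counting interval or detection limit is given for that reason. FPKM in its usual form divides by the library total, and small RNA genes took 71.2% to 83.7% of the summed FPKM in the CK-p25 neuron libraries, 54.4% to 75.4% in the P301S neuron libraries and 0.0991% to 0.184% in microglia. The median-ratio factors between the libraries of a set were nonetheless 1.008 to 1.017, 1.008 to 1.018 and 1.006 to 1.026 in these sets, so the deposited values already share a median scale, and median-ratio rescaling moves little and is no test of the scale. A gene can also be listed at exactly 0 while it is abundant in sister libraries. Apoe and Ctsd, which microglia express strongly, were listed at 0 in 3 and 7 of the 12 microglia libraries, so an exact 0 in these files is reported only as a listing.

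Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. No pair of files held identical values, and the correlation between replicates of a group over the tested genes was 0.878 to 0.912 in CK-p25 neurons, 0.837 to 0.886 in P301S neurons and 0.946 to 0.976 in microglia.

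The 3 sets (CK-p25 neurons, P301S neurons, CK-p25 microglia) were analysed separately. Genes with a mean FPKM of at least 1 over the libraries of a set were kept, which left 12567, 12239 and 10394 genes. Values were transformed to log2(FPKM + 1), so a log2 change understates the change of low genes. A linear model with 3 groups sharing 1 estimate of the spread was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend. P-values are two-sided and were adjusted over the tested genes of a comparison by the Benjamini-Hochberg method, with a threshold of 0.05. Each set gave 3 comparisons: untreated model against control, stimulated against untreated model, and stimulated model against control. The last shares its control libraries with the first, and chance values for such shared controls were simulated.

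A total of 29 gene lists were fixed before the data were examined. They cover pathways, cell states and markers of the cell types that a sort could hold. Lists with at least 5 tested members were compared with all other genes by limma's camera test with a preset correlation between genes of 0.01, adjusted over the lists and comparisons of a set. The test was repeated with a correlation estimated for each list. The counts of members called within a list are given over all genes and adjusted over the list alone.

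The genes named were fixed by rule before the data were examined. They are Cdk5r1, Mapt, Prnp and Camk2a in neurons, since the transgenes carry sequence of the first pair or promoters of the second. For each comparison of model with control and of stimulated with untreated, they are the 10 largest rises and the 10 largest falls past the threshold whose groups do not overlap in any library, leaving out small RNAs, predicted genes, clone names and pseudogenes. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were taken. The members of a list with the smallest p are named with it. Values of some genes are not reported here, though they entered every test and count. The reads of near-identical paralogs such as the H2-Q genes could be split by the authors' counting, and their values are uncertain.

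The model was tested on simulated data with 200 changed genes. For the comparisons of model with control in CK-p25 neurons, P301S neurons and microglia it recovered 32.7%, 27.3% and 23.5% of genes changed by 0.5 on the log2 scale, 74.5%, 67.7% and 76.8% of those changed by 1, and 93.5%, 94.1% and 96.8% of those changed by 2. False calls made up 4.82%, 4.83% and 5.57% of the calls. The simulated genes varied independently and without a batch, and microglia had 2802 real calls, so these rates need not hold for the data.

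The replicate numbers were checked as a pairing by the correlation of same-numbered libraries' deviations from their group means. Between stimulated and untreated microglia, all 4 pairs correlated at 0.105 to 0.338. Libraries of different numbers reached 0.326 there (median −0.209), and 1 library correlated best with its own number. The batch given next also sets replicates 1 and 2 apart from 3 and 4, so a pairing cannot be told apart from it. A block for the replicate number changed no count there. In the other 8 comparisons at least 1 pair fell under 0.1. A batch was also read from the values, as the sign of the first component of the deviations from group means. It parted microglia replicates 1 and 2 from 3 and 4 in every group. In P301S neurons it parted wild type 1 to 3, untreated 1 to 3 and stimulated 1 and 2 from the rest. This split was read from the values alone and need not be a technical batch. In microglia the component ran from −0.0911 to 0.0997 in control libraries and from −0.465 to 0.433 in CK-p25 libraries. A technical batch and a graded difference among the CK-p25 libraries cannot be told apart there.

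The alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, median-ratio rescaling of each library, 2 groups in the fit, library weights, a block for the replicate number, removal of small RNAs and unnamed genes, and each library left out in turn. Alternatives chosen after seeing the data were exact zeros taken as missing in genes of at least 10 FPKM elsewhere, a mean FPKM of at least 5, the batch read from the values as a block, each side of that batch alone, and the omission of 1 stimulated neuron library.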

Results

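The series measured RNA in neurons and microglia of the mouse visual cortex in mouse models of neurodegeneration, with and without gamma entrainment using sensory stimuli (GENUS), here daily light flicker at 40 Hz. CK-p25 mice make p25, a truncated activator of the kinase Cdk5, in forebrain neurons when a tetracycline-controlled transgene is switched on, and were induced for 6 weeks. P301S mice carry human tau with a mutation that causes frontotemporal dementia, under the Prnp promoter, and were 8 months old. GENUS lasted 43 days in CK-p25 and 22 days in P301S mice. Neuronal nuclei came from control (CK, n = 5 libraries), untreated CK-p25 (n = 5) and GENUS-treated CK-p25 mice (n = 4), and from wild type (n = 6), untreated P301S (n = 6) and GENUS-treated P301S mice (n = 5). Microglia came from CK, untreated CK-p25 and GENUS-treated CK-p25 mice (n = 4 libraries each). Here n counts libraries, not animals. Between 12103 and 12555 genes reached 1 FPKM in a CK-p25 neuron library, 11754 to 12139 in a P301S neuron library and 9942 to 10393 in a microglia library. Read depth is unknown.

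The genes from which the transgenes were built were examined first. Mouse Cdk5r1, the source of p25, was at 27.1 ± 4.66 FPKM (SD, n = 5) in CK neurons and 25.01 ± 1.56 (n = 5) in untreated CK-p25 neurons. Mapt, which encodes tau, was at 55.2 ± 5.00 FPKM (n = 6) in wild type and 57.3 ± 3.86 (n = 6) in P301S neurons. Neither difference passed the test over these 4 genes alone (adjusted p = 0.371 and 0.644). The transgenes are human sequence and the files list mouse symbols, so these values need not measure transgene expression. Prnp, whose promoter drives the P301S transgene, was higher in P301S than in wild type neurons, at 89.7 ± 13.7 against 63.4 ± 3.84 FPKM, a log2 change of 0.48 (SE 0.09). Its limma p adjusted over the 4 genes alone was 0.000135, and 0.207 over all genes. Whether these Prnp values come from the mouse gene itself or in part from the P301S transgene was not tested. Over the 4 genes alone, CK-p25 neurons also had higher Prnp (log2 change 0.33, SE 0.12, adjusted p = 0.0295) and lower Camk2a (log2 change −0.22, SE 0.07, adjusted p = 0.0215), a kinase of excitatory synapses whose promoter drives the inducer in these mice. Neither passed over all genes (adjusted p = 0.290 and 0.197).

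The first comparison asked what 6 weeks of p25 did to cortical neurons. Cell cycle genes were higher in CK-p25 neuronal nuclei than in CK nuclei, together with interferon-stimulated genes and Gfap. Mcm3, a subunit of the helicase that opens DNA for replication, was listed at 0 in 4 CK libraries and at 0.303 FPKM in CK replicate 3, against 9.56 ± 1.72 FPKM in untreated CK-p25 nuclei (log2 change 3.31, SE 0.17, adjusted p = 8.21e-08). Ifit1, an antiviral protein induced by interferon, rose from 0.676 ± 0.705 to 9.70 ± 2.39 FPKM (log2 change 2.73, SE 0.30). Gfap, the intermediate filament of astrocytes, rose from 1.96 ± 0.888 to 15.5 ± 2.91 FPKM (log2 change 2.52, SE 0.30). The other rises among the 10 largest were of Mcm2 (log2 change 2.17) and Cdc45 (1.94), which like Mcm3 belong to the cell cycle list, and of Pole (2.36), Rad51ap1 (2.22), Timeless (2.10), Clspn (2.06) and Cenph (1.94), which do not. Pole, Rad51ap1, Mcm2 and Cenph were each listed at 0 in 1 CK library and Clspn in 2. In all, 127 of 12567 genes passed the test, 112 higher and 15 lower, and 62 of the rises were at least 2-fold. At an unadjusted p under 0.05 there were 1404 genes, against 628 by chance. The groups did not overlap in any library for 123 of the 127, and for 2.85% of all tested genes, where chance gives 0.794%. The count was 77 without untreated CK-p25 replicate 2 and 81 without replicate 4, 71 with 2 groups in the fit, and 57 with a mean of at least 5 FPKM, which removes many of the low genes. The 15 lower genes became 4 without CK replicate 2 or untreated replicate 2, 6 without CK replicate 3 or untreated replicate 4, 9 without CK replicate 1 or 5 or untreated replicate 3, 27 without untreated replicate 1, 6 with 2 groups and 7 with the higher minimum.

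**Figure D1:**
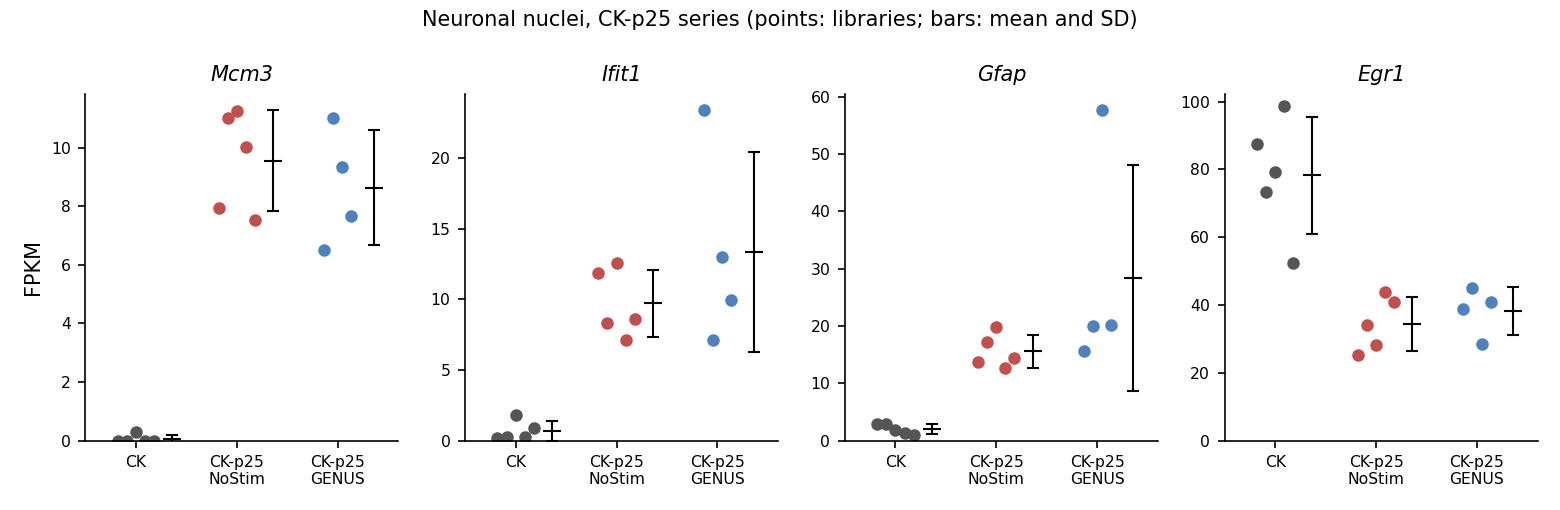
FPKM of Mcm3, Ifit1, Gfap and Egr1 in each neuronal library of the CK-p25 series on linear axes from 0, where each point is 1 library and the bar gives the mean and SD of the group. Every CK library lies below every CK-p25 library for Mcm3, Ifit1 and Gfap, and above it for Egr1, and 1 GENUS library stands at 57.7 FPKM for Gfap.

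Among the genes that fell in CK-p25 neurons was Egr1, a transcription factor induced by neuronal activity, from 78.3 ± 17.3 to 34.5 ± 7.99 FPKM (n = 5 each; log2 change −1.16, SE 0.18, adjusted p = 0.00457). Rpap3, a cofactor of the HSP90 chaperone, went from 18.8 ± 0.430 to 12.7 ± 0.737 FPKM (log2 change −0.54, SE 0.07, adjusted p = 0.000841). The remaining falls were Nudt2 (log2 change −1.56, listed at 0 in 1 untreated CK-p25 library), Usb1 (−0.92), Ccdc71l (−0.72), the tubulins Tubb2a (−0.69) and Tubb3 (−0.65), the sorting nexin Snx1 (−0.64), Fdft1 (−0.62), which makes squalene for cholesterol synthesis, and Rab3ip (−0.51). Egr1 and Rpap3 kept the call whichever library was left out. Each of the other 8 lost it in 5 to 10 of the 10 runs that left out 1 library, each of the 5 CK and 5 untreated CK-p25 libraries ended at least 2 of these calls, and the highest adjusted p per gene lay between 0.0587 and 0.120.

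Of the gene lists, the cell cycle list had the lowest adjusted p in CK-p25 neurons. It had 14 of 29 tested members higher and 0 lower (21 higher and 1 lower adjusted over the list alone), a median log2 change of 1.02 and a camera adjusted p of 7.71e-29, or 0.00175 with an estimated correlation. Mcm5, of the same helicase as Mcm3, went from 0.694 ± 0.259 to 5.18 ± 0.855 FPKM (log2 change 1.87). All 19 tested members of the type I interferon list had estimates above 0, with 5 called (15 adjusted over the list alone) and a median log2 change of 0.90 (adjusted p = 6.35e-18, and 0.00798 with an estimated correlation). Other listed members did not reach the minimum mean FPKM. Members near 0 in CK nuclei reach it only if they are higher in CK-p25 nuclei, so the shared direction comes in part from the filter. The list of complement and Fc receptors had 1 of 5 members called (2 adjusted over the list alone), the complement subunit C1qc, and a median log2 change of 0.90 (adjusted p = 0.00147, and 0.0423 with an estimated correlation). C1qc was listed at 0 in all 5 CK libraries and was at 1.39 ± 0.578 FPKM in untreated CK-p25 nuclei. Tested microglia markers were also higher in these neuronal libraries, with a median log2 change of 0.84 and 1 of 7 members called, again C1qc (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00359, and 0.0569 with an estimated correlation). Of the 20 listed markers, Cx3cr1, P2ry12, P2ry13, Aif1 (1.68 to 0.240 FPKM) and Laptm5 had lower means in untreated CK-p25 than CK nuclei, and the rest higher ones. Genes near 0 in CK nuclei pass the filter, a mean over all 3 groups, only through the CK-p25 libraries. This can raise the medians of the cell cycle, interferon, complement and microglia marker lists. The astrocyte list was not called, with 1 of 20 members past the test, Gfap, and a median log2 change of −0.02 but a mean of 0.12 (adjusted p = 0.525). The oligodendrocyte precursor list had a median of −0.16 and a mean of 0.05 over 5 members (adjusted p = 0.609), and oligodendrocyte markers a median of −0.22 over 10 (adjusted p = 0.05001, which did not pass). Homeostatic microglia genes (median 0.00, with 1 of 13 members higher, Jun, and 4 adjusted over the list alone) and inflammatory genes (−0.14) were not called (adjusted p = 0.259 and 0.246).

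Lower in CK-p25 neurons were the immediate early genes, with a median log2 change of −0.56 over 28 members (adjusted p = 1.24e-07, and 0.159 with an estimated correlation). Egr1 was the 1 member that fell over all genes, 7 fell adjusted over the list alone, and Jun, which encodes an AP-1 subunit, went the other way, from 5.19 ± 1.46 to 10.7 ± 1.18 FPKM (adjusted p = 0.00677). Cholesterol synthesis genes had a median of −0.47, with 1 of 19 lower (7 adjusted over the list alone; camera adjusted p = 5.65e-08, and 0.0892 with an estimated correlation). Oxidative phosphorylation genes had a median of −0.28 and 37 of 43 estimates below 0, with 0 of them past limma's test (camera adjusted p = 7.62e-07, and 0.0892 with an estimated correlation). The axonal transport and cytoskeleton list had 2 of 37 members lower, Tubb2a and Tubb3 (6 adjusted over the list alone), and a median of −0.12 (camera adjusted p = 2.86e-09, and 0.0643 with an estimated correlation). The lists of neuronal markers and of excitatory neuron markers had medians of −0.11 and −0.08 (adjusted p = 4.88e-05 and 0.0264, and 0.0569 and 0.159 with an estimated correlation), with 1 and 0 members lower (4 and 0 adjusted over the list alone). Synaptic vesicle genes had a median of −0.06, ribosomal protein genes −0.14 and genes of the unfolded protein response −0.12 (adjusted p = 0.0130, 0.0325 and 0.0345, and 0.313, 0.129 and 0.357 with an estimated correlation). The lists of p53 targets (median 0.18), class I antigen presentation (0.21), genes of disease-associated microglia (0.23) and lysosomal genes (0.15) were higher, with adjusted p of 0.0210, 0.0264, 0.0130 and 0.0252. With an estimated correlation these were 0.0951, 0.0892, 0.129 and 0.266. Brca1, a DNA repair protein, was their only member called over all genes, and adjusted over each list alone there were 1, 1, 0 and 5 higher members, and 1 lower lysosomal one. Postsynaptic density genes (median 0.00) and inhibitory neuron markers (0.04) were not called (adjusted p = 0.355 and 0.525), and the mean of the former was −0.02. The p53 call ended without CK replicate 1, 2 or 3 or untreated replicate 3 or 5, the unfolded protein call without CK replicate 5 or untreated replicate 2, 3 or 5, and the ribosomal call without CK replicate 2 or untreated replicate 2 or 4 (adjusted p up to 0.0976, 0.225 and 0.0916). The excitatory neuron call ended without CK replicate 3 or untreated replicate 2 or 5, the lysosomal call without CK replicate 1 or 5 or untreated replicate 2, the synaptic vesicle call without CK replicate 2 or untreated replicate 5, and the class I call without CK replicate 1 (up to 0.0673, 0.110, 0.121 and 0.0589).

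The second comparison asked whether GENUS changed gene expression in CK-p25 neurons. With limma, 0 of 12567 genes passed between GENUS-treated (n = 4) and untreated (n = 5) CK-p25 nuclei, and 933 had an unadjusted p under 0.05, against 628 by chance. Mcm3 was at 8.63 ± 1.96 FPKM after GENUS and Egr1 at 38.3 ± 7.03, both differing from untreated CK-p25 nuclei by less than the spread between libraries. The genes with the smallest p did not pass and are given as values. Sik3, a salt-inducible kinase, was at 24.0 ± 0.538 against 17.1 ± 1.74 FPKM (log2 change 0.47, SE 0.09), with Ppil2 (0.42), Sdccag8 (0.38), Specc1 (0.43) and Ttyh3 (0.30). On the lower side were Pde10a, a striatum-enriched phosphodiesterase, at 22.8 ± 3.13 against 39.9 ± 4.03 FPKM (log2 change −0.78, SE 0.14), Pak7 (−0.59), Csgalnact1 (−0.64), Coq7 (−1.15) and Zfp945 (−0.42). The lowest adjusted p was 0.253. The correlation across genes between the effect of p25 and the effect of GENUS, with the untreated libraries split between them, was 0.060 (permutation p = 0.06 over 100 labellings), and genes are not independent replicates. It was 0.056 without CK replicate 3 and 0.1002 without untreated CK-p25 replicate 4 (permutation p = 0.04 and 0.0143).

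Of 24 lists, 8 were higher in GENUS-treated than untreated CK-p25 neurons with the preset correlation and 0 with an estimated one. Astrocyte markers were higher after GENUS, with a median log2 change of 0.59 over 20 members and 0 members past limma's test (camera adjusted p = 9.16e-07, and 0.188 with an estimated correlation). The median was 0.31 without GENUS replicate 3, in which Gfap stood at 57.7 FPKM against 15.6 to 20.1 in the other 3. Oxidative phosphorylation genes (median 0.17 over 43), ribosomal protein genes (0.21 over 41) and cytoskeletal genes (0.08 over 37) were higher (adjusted p = 0.000520, 0.0196 and 0.00268, and 0.184, 0.1001 and 0.284 with an estimated correlation). So were inhibitory neuron markers (0.19), homeostatic microglia genes (0.27), complement genes (0.40) and microglia markers (0.40), with adjusted p of 0.00338, 0.00290, 0.00543 and 0.00478, and of 0.313, 0.0614, 0.0606 and 0.0573 with an estimated correlation. The oxidative phosphorylation, ribosomal and cytoskeletal lists were lower in untreated CK-p25 than CK neurons. Both comparisons share the untreated libraries, whose chance deviations move the p25 and GENUS effects in opposite directions. The list tests did not split these libraries, so they cannot show a reversal. Without GENUS replicate 3 the count of called lists was 3 in place of 8, with 4 calls ended and the complement list left with fewer than 5 tested members and so not tested, and without GENUS replicate 2 the count was 13. Over all genes and adjusted over the list alone, 0 members of these lists passed, except 1 microglia marker adjusted over the list alone. The cytoskeletal call ended without untreated replicate 2 or GENUS replicate 3, the ribosomal call without untreated replicate 4 or GENUS replicate 3, the inhibitory neuron call without GENUS replicate 3 or 4, and the homeostatic call without GENUS replicate 3 (adjusted p up to 0.0616, 0.0788, 0.0761 and 0.0521). The cell cycle (median 0.06), interferon (0.18) and immediate early lists (−0.15) were not called (adjusted p = 0.364, 0.173 and 0.0882). Median and mean differed in sign for lysosomal genes (−0.02 and 0.01) and excitatory neuron markers (0.02 and −0.05), neither called.

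Compared with CK nuclei, GENUS-treated CK-p25 nuclei had 183 genes past the test, 135 higher and 48 lower. The cell cycle list was again called higher, with 14 of 29 members higher and a median log2 change of 1.03 (adjusted p = 6.84e-26, and 0.00175 with an estimated correlation). The interferon list had 8 of 19 members higher and a median of 1.22, complement genes 3 of 5 (median 1.46), microglia markers 3 of 7 (1.20) and class I antigen presentation 1 of 14 (0.39). Their adjusted p were 1.30e-15, 7.29e-06, 9.51e-06 and 0.00287, and 0.0107, 0.00798, 0.00798 and 0.0423 with an estimated correlation. As in untreated nuclei, genes near 0 in CK pass the filter only through CK-p25 libraries, which can raise such medians. Immediate early genes had 1 member higher and 4 lower of 28, with a median of −0.67 (adjusted p = 2.76e-09, and 0.124 with an estimated correlation). Adjusted over the list alone, the counts were 22 cell cycle, 12 interferon, 4 complement, 5 microglia marker and 2 class I genes higher, and 1 immediate early gene higher and 12 lower. Another 9 lists were called with the preset correlation only. Astrocyte markers (median 0.61), homeostatic microglia genes (0.37), disease-associated microglia genes (0.25), inhibitory neuron markers (0.19) and lysosomal genes (0.11) were higher, with adjusted p of 0.252, 0.0569, 0.0892, 0.313 and 0.299 with an estimated correlation. Cholesterol synthesis (−0.43), neuronal markers (−0.11), excitatory neuron markers (−0.10) and cytoskeletal genes (−0.05) were lower, with adjusted p of 0.0951, 0.0892, 0.124 and 0.313 with an estimated correlation. The lysosomal call ended without CK replicate 1, 2 or 5 or GENUS replicate 3, the excitatory call without GENUS replicate 3 and the inhibitory call without CK replicate 1 (adjusted p up to 0.259, 0.0521 and 0.0657). Median and mean differed in sign for the unfolded protein response (0.04 and −0.08) and postsynaptic genes (0.02 and −0.03), and the ribosomal test was on the lower side of a median of 0.03, none of them called.

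The count of genes was 120 without CK replicate 1, 113 without CK replicate 4, 92 without GENUS replicate 3, 109 without GENUS replicate 4, 85 with 2 groups in the fit and 109 with a mean of at least 5 FPKM. The 48 lower genes became 15 without GENUS replicate 3, 23 to 30 without any of the other libraries except CK replicate 5 (42), and 16 with 2 groups. Of the genes called in CK-p25 untreated nuclei, 81 higher and 3 lower ones were also called here, where independent lists would share 1.20 and 0.0573. Both comparisons use the same CK libraries. The correlation of their log2 changes was 0.61, against 0.48 in simulated unchanged groups and 0.18 with the controls split. The covariance was 0.0963 against 0.0551 in the simulation.

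In P301S neurons the question was what mutant tau did. A single gene passed between untreated P301S and wild type nuclei (n = 6 each). Nmb, the peptide neuromedin B, was at 8.00 ± 1.28 against 2.51 ± 1.07 FPKM (log2 change 1.41, SE 0.20, adjusted p = 0.0213), and at 4.92 ± 0.927 FPKM (n = 5) after GENUS. There were 690 genes with an unadjusted p under 0.05, against 612 by chance. Prnp, Kifc2, Trappc2l and Bglap3 had the next smallest p among the higher genes and did not pass, with log2 changes of 0.48, 0.37, 1.65 and 1.57. Trappc2l was listed at 0 in 2 wild type libraries and Bglap3 in 3. Among the lower genes were Rabac1 (−0.54), Ina (−0.45), Cage1 (−0.57), Gpx1 (−1.498) and Eif3d (−0.71), none past the test. The call on Nmb was lost without wild type replicate 6 or untreated P301S replicate 2, 3, 4 or 5 (adjusted p up to 0.101), and with 2 groups in the fit or a pseudocount of 0.1, while leaving out untreated P301S replicate 1 gave 2 genes. Within the libraries on each side of the batch read from the values (replicates 1 to 3 and 4 to 6), 5 and 1 genes passed, and the effects on the 2 sides correlated across genes at 0.08.

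Immediate early genes had a median log2 change of −0.48 over 29 members, of which 3 fell adjusted over the list alone and 0 over all genes in limma's test (camera adjusted p = 2.08e-09, and 0.490 with an estimated correlation). The AP-1 subunit gene Jun was at 4.16 ± 1.52 against 8.01 ± 2.12 FPKM, Egr4 at 1.80 ± 1.004 against 5.19 ± 2.88 and Fos at 1.34 ± 0.760 against 7.56 ± 6.47. In all, 8 of 22 lists were lower with the preset correlation and 0 with an estimated one. Medians were −0.20 for the unfolded protein response, −0.21 for ribosomal proteins, −0.18 for genes of disease-associated microglia, −0.14 for inhibitory neuron markers, −0.12 for neuronal markers, and −0.06 for synaptic vesicle and for cytoskeletal genes. Their adjusted p were 0.000889, 0.0163, 0.0420, 0.0340, 0.0163, 0.0163 and 0.0163 in this order, and 0.695, 0.741, 0.490, 0.725, 0.490, 0.490 and 0.490 with an estimated correlation. Adjusted over the list alone, the cytoskeletal gene Ina was the 1 lower member of these 7 lists. Cell cycle (median 0.01) and interferon genes (0.00) were not called (adjusted p = 0.618 and 0.972). Oligodendrocyte precursor markers had a median of −0.02 and a mean of 0.15 (adjusted p = 0.813). The count was 4 without wild type replicate 4, 5 without replicate 5, 3 without replicate 6, and 4 without untreated P301S replicate 1. The immediate early and unfolded protein lists kept the call whichever library was left out. The inhibitory neuron call ended without wild type replicate 4, 5 or 6 or untreated P301S replicate 1, 3 or 4, the disease-associated microglia call without wild type replicate 4, 5 or 6 or untreated replicate 1 or 5, and the ribosomal call without wild type replicate 4, 5 or 6 or untreated replicate 3 (adjusted p up to 0.255, 0.214 and 0.155). The neuronal marker call ended without wild type replicate 4 or 6 or untreated replicate 1, the synaptic call without wild type replicate 6 or untreated replicate 1, and the cytoskeletal call without wild type replicate 3 (up to 0.0803, 0.0724 and 0.0739).

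GENUS in P301S neurons (n = 5 against 6 untreated) gave 0 of 12239 genes past limma's test, and 524 at an unadjusted p under 0.05, below the 612 expected by chance. The genes with the smallest p did not pass. Higher ones were Cetn3, a centriole protein (42.3 ± 7.38 against 26.5 ± 5.67 FPKM, log2 change 0.66), Tuba1b (1.21), Brd9 (0.25), Sult2b1 (1.19) and Rabac1 (0.42). Tuba1b was listed at 0 in 1 untreated library and Sult2b1 in 3. Lower ones were Bean1 (−0.81), Zbtb25 (−0.69), Pla2g4e (−0.74) and Ift46 (−0.62), and Bglap3, which was listed at 0 in all 5 GENUS libraries and at 1.33 to 11.01 FPKM in untreated ones. Of 22 lists, 3 were higher, each with the preset correlation alone. They were immediate early genes (median 0.29), the unfolded protein response (0.25) and cytoskeletal genes (0.07), with adjusted p of 0.000889, 0.000514 and 0.0163, and of 0.725, 0.631 and 0.490 with an estimated correlation. These 3 were among the 8 lists lower in untreated P301S than wild type neurons. Both comparisons share the untreated libraries, whose chance deviations move the tau and GENUS effects in opposite directions. The list tests did not split these libraries, so they cannot show a reversal. Over all genes and adjusted over the list alone, 0 members of these lists passed. Inflammatory genes had a median of 0.12 and a mean of −0.03 and were not called (adjusted p = 0.862). Without untreated P301S replicate 5, 7 lists were called, and 5 without untreated replicate 6 or GENUS replicate 2. The call on immediate early genes ended without GENUS replicate 1 (adjusted p = 0.106) and that on cytoskeletal genes without GENUS replicate 5 (adjusted p = 0.128). On the 2 sides of the batch, 3 and 4 genes passed, with effects that correlated across genes at 0.01. The correlation across genes of the tau and GENUS effects, split as above, was −0.042 (permutation p = 0.3).

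Between GENUS-treated P301S and wild type neurons 0 genes passed limma's test, 701 had an unadjusted p under 0.05, and Prnp had the smallest adjusted p, 0.0525 (log2 change 0.60, SE 0.09, 96.7 ± 7.15 against 63.4 ± 3.84 FPKM). Immediate early genes and cholesterol synthesis genes were called lower, with medians of −0.22 and −0.13 (adjusted p = 0.0420 and 0.0365, and 0.889 and 0.490 with an estimated correlation). The first call ended without wild type replicate 3, 5 or 6 or GENUS replicate 3, 4 or 5, and the second without wild type replicate 5 or 6 or GENUS replicate 3, 4 or 5 (adjusted p up to 0.520 and 0.163). On each side of the batch 1 gene passed. Effects in CK-p25 and P301S neurons were compared across 12040 genes. Pearson's correlation was 0.015 for the model effects and −0.026 for the GENUS effects (permutation p = 0.78 and 0.69, 100 labellings each), with 0 genes called in both CK-p25 and P301S neurons by limma. Spearman's was 0.0635 and 0.0609 (permutation p = 0.40 and 0.04), so for the GENUS effects the sign depended on the measure. Of the 1288 and 912 genes with an unadjusted p under 0.05 in CK-p25 neurons, 57.3% and 54.4% had the same sign in P301S neurons (permutation p = 0.27 and 0.26). The p-values of these last 2 measures were computed after their values were seen, and over all 6 values the smallest adjusted p was 0.24, for Spearman's correlation of the GENUS effects. Genes are not independent replicates. The CK-p25 libraries had 329 to 412 FPKM of Xist and Ddx3y listed at 0, and the P301S libraries at most 0.136 FPKM of Xist and 8.28 to 14.3 of Ddx3y, so the model cannot be told apart from the sex of the animals in this comparison. Without CK replicate 1 or 2 or wild type replicate 4, 5 or 6 Pearson's correlation of the model effects was below 0, and without untreated CK-p25 replicate 1 that of the GENUS effects was above 0.

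In microglia of untreated CK-p25 mice, 2802 of 10394 genes differed from CK microglia (n = 4 each), 1672 higher and 1130 lower, and 671 rises and 246 falls were at least 2-fold. The 10 largest rises included 5 genes of the disease-associated list, Spp1, Cst7, Axl, Lpl and Gpnmb. Spp1 (osteopontin) had a log2 change of 7.19 (SE 0.63), Cst7, a cystatin, of 6.80 (SE 0.35), from 22.4 ± 5.65 to 2721 ± 1205 FPKM, and the receptor kinase Axl, which clears dying cells, of 5.36 (SE 0.22), from 6.42 ± 1.74 to 299 ± 47.0 FPKM (adjusted p = 2.91e-09). Cxcl13, a B cell chemokine, rose by 6.52 on the log2 scale, Ifi27l2a by 5.34, the lipoprotein lipase Lpl by 5.31, Gpnmb by 5.24 and Cox6a2 by 5.63. Cxcl13 was listed at 0 in 1 CK library and Gpnmb in 2. H2-Q7 (5.99) and H2-Q8 (5.20), class I genes with near-identical paralogs, are uncertain. The largest falls were of Bank1 (−3.47), Slco4a1 (−3.34), the prostaglandin receptor Ptger3 (−3.33), Gpr165 (−3.29), Gp9 (−3.28), Upk1b (−3.26), Serpinf1 (−3.21), Tmem204 (−3.20), Tspan18 (−2.50) and Ecscr (−2.49). Ptger3 was listed at 0 in 3 untreated and 3 GENUS CK-p25 libraries. Each of these 20 kept its call with any library left out. There were 3859 genes at an unadjusted p under 0.05, against 519.7 by chance. The groups did not overlap in any library for 2476 of the called genes, and for 27.9% of all tested genes, where chance gives 2.86%. Within the batches read from the values, replicates 1 and 2 and replicates 3 and 4, there were 1971 and 1409 calls, with effects that correlated across genes at 0.73.

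**Figure D2:**
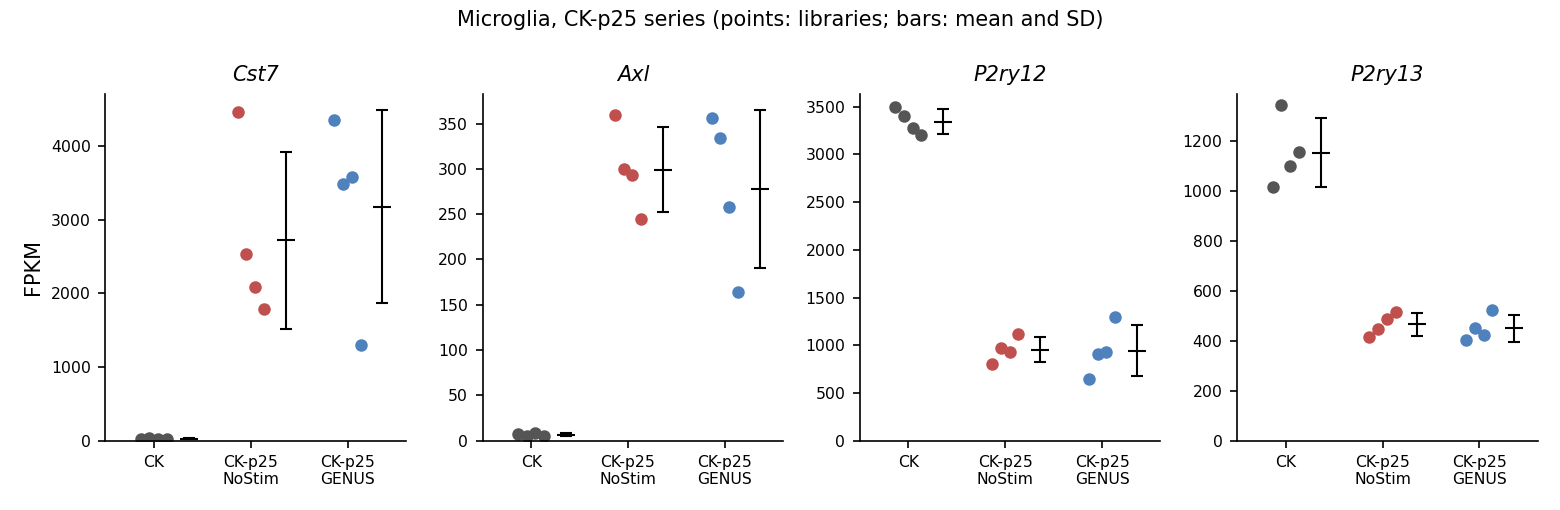
FPKM of Cst7, Axl, P2ry12 and P2ry13 in each microglia library on linear axes from 0, where each point is 1 library and the bar gives the mean and SD of the group. Cst7 and Axl lie higher in all 8 CK-p25 libraries than in the 4 CK libraries, P2ry12 and P2ry13 lie lower, and the GENUS and untreated points overlap.

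By list, all 36 tested interferon genes rose in CK-p25 microglia, with a median log2 change of 2.79, as did 18 of 19 class I antigen presentation genes (1.71) and 28 of 31 genes of disease-associated microglia (2.19). Examples are Oasl2, an antiviral synthetase-like protein (2.31 ± 0.787 to 88.1 ± 17.0 FPKM, log2 change 4.76), and Clec7a, a pattern receptor (17.6 ± 6.85 to 571 ± 80.5 FPKM, 5.00). Of 41 ribosomal protein genes, 40 rose (median 1.06). Of 26 homeostatic microglia genes, 19 fell and 2 rose, Serpine2 and Trem2, with a median of −0.69. P2ry12, a purine receptor of resting microglia, went from 3346 ± 129 to 953 ± 131 FPKM (log2 change −1.82) and P2ry13 from 1154 ± 139 to 466 ± 45.1 FPKM (−1.30). Camera gave adjusted p of 1.53e-32, 1.03e-17, 3.57e-25, 2.58e-34 and 6.91e-09 for these 5 lists in this order, and 0.120 for each with an estimated correlation. Adjusted over the list alone, 36, 18, 28 and 40 members of the first 4 rose and 1 disease-associated gene fell, and 20 homeostatic genes fell and 2 rose.

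Further lists higher in CK-p25 microglia were inflammatory cytokines and NF-kB targets (22 of 32 higher and 3 lower, median 1.29), complement and Fc receptors (13 of 18, 0.70) and lysosomal genes (27 of 36 higher and 2 lower, 0.85). Their adjusted p were 9.86e-10, 6.24e-07 and 1.01e-11, and 0.143, 0.143 and 0.223 with an estimated correlation. C3 rose from 0.521 ± 0.250 to 24.8 ± 8.32 FPKM and the sensor Tlr2 from 87.9 ± 7.66 to 514 ± 62.5. Class II antigen presentation genes had 9 of 14 members higher and 1 lower (median 0.86), the cell cycle list 20 of 33 higher (0.94), oxidative phosphorylation 22 of 43 (0.28), p53 targets 10 higher and 1 lower of 25 (0.48), and immediate early genes 12 higher and 1 lower of 26 (0.72). Camera gave adjusted p of 0.00241, 5.14e-07, 1.43e-06, 0.0178 and 0.00405 for these, and 0.244, 0.298, 0.298, 0.174 and 0.665 with an estimated correlation. Adjusted over the list alone, the counts were 24 higher and 4 lower inflammatory, 13 complement, 28 and 2 lysosomal, 9 and 1 class II, 22 cell cycle, 22 oxidative phosphorylation, 13 and 1 p53 and 13 and 1 immediate early genes. Cdkn1a, the p21 inhibitor of cell division, rose from 11.7 ± 3.57 to 81.8 ± 15.8 FPKM. Neuronal markers were lower (3 of 5, the same number adjusted over the list alone, median −1.39, camera adjusted p = 0.0244, and 0.391 with an estimated correlation). That call ended without CK replicate 3 (adjusted p = 0.0598), and that on Nrgn within it without CK replicate 3 or 4 or untreated CK-p25 replicate 1 or 3 (up to 0.0606). Markers of monocytes, neutrophils and perivascular macrophages (median −0.06), astrocytes (−0.01), oligodendrocytes (−0.69), endothelial and mural cells (−0.47) and lymphocytes (1.32) were not called (adjusted p from 0.281 to 0.969). Mean and median differed in sign for astrocytes (mean 0.13), and the test was on the higher side for endothelial and mural cells (mean −0.21).

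Ctsd, a lysosomal protease, and Apoe, the apolipoprotein, cannot be compared in microglia. Ctsd was listed at 0 in all 4 GENUS libraries and in untreated CK-p25 replicates 1 to 3, at 25072 FPKM in untreated replicate 4, and at 10102 to 14149 FPKM in CK. Apoe was listed at 0 in untreated replicate 1 and GENUS replicates 1 and 2, at 8977 to 33132 FPKM in the other 5 CK-p25 libraries and at 793 to 1546 FPKM in CK. Ctsd is the 1 lower gene in the count for disease-associated microglia genes and 1 of the 2 lower in the lysosomal list, the other being Npc1.

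**Figure D3:**
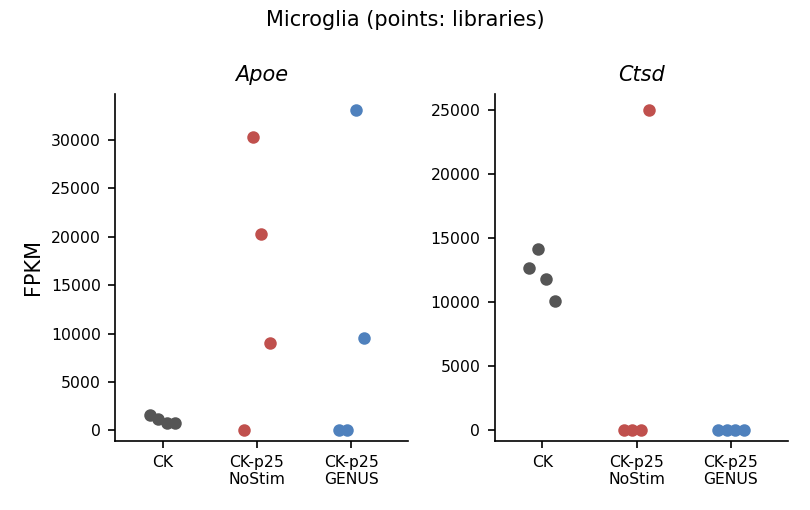
FPKM of Apoe and Ctsd in each microglia library on linear axes, where each point is 1 library. Ctsd is at 0 in 7 of 8 CK-p25 libraries and Apoe in 3, beside values of up to 25072 and 33132 FPKM.

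GENUS in CK-p25 microglia (n = 4 against 4) gave 0 of 10394 genes past limma's test, and 762 at an unadjusted p under 0.05, against 519.7 by chance. Axl was at 278 ± 87.2 FPKM after GENUS and Cst7 at 3181 ± 1316, and P2ry12 at 943 ± 266, differing from the untreated by less than the spread between libraries. The genes with the smallest p did not pass. They were Max (log2 change 0.69), Rab5c (0.53), Eif4a1 (0.37), Raly (0.54) and Vapb (0.66) among the higher, and Fbxw11 (−0.45), Rock2 (−0.53), Spata13 (−0.40), Slc35a3 (−0.50) and Clasp2 (−0.62) among the lower. Of 25 lists, 4 were called higher with the preset correlation. Every one of 41 ribosomal protein genes had an estimate above 0, with a median of 0.22, and 39 of 43 oxidative phosphorylation genes did, with a median of 0.13 (camera adjusted p = 2.06e-20 and 4.28e-09, and 0.128 and 0.223 with an estimated correlation). The unfolded protein response (median 0.21) and immediate early genes (0.12) had adjusted p of 0.00252 and 0.0263, and 0.552 and 0.826 with an estimated correlation. Over all genes and adjusted over the list alone, 0 members of these 4 lists passed. Disease-associated microglia genes had a median of 0.04 and a mean of −0.17, and were not called (adjusted p = 0.473). That mean includes Apoe and Ctsd, each listed at 0 in more GENUS than untreated libraries, so it does not show a fall of the list. The unfolded protein call ended without untreated replicate 1 or GENUS replicate 4, the immediate early call without untreated replicate 1 or 2 or GENUS replicate 3 or 4 (adjusted p up to 0.537 and 0.657), and 8 lists were called without untreated replicate 4. Within the batches of replicates 1 and 2 and of 3 and 4, 5 and 3 genes passed and the effects correlated across genes at 0.00. The correlation across genes of the p25 and GENUS effects was 0.114 (exact permutation p = 0.429 over all 70 labellings, which mix pairs and batches). The p was 0.312 in an exact permutation test over the 16 labellings that keep the numbered pairs, which cannot go below 0.0625, and 0.444 over the 36 that keep the batch, both chosen after seeing the data.

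Compared with CK, GENUS-treated CK-p25 microglia had 3195 genes past the test, 1802 higher and 1393 lower, and 2220 and 1740 within the 2 batches. All 36 interferon genes were higher (median 3.04), 29 of 31 genes of disease-associated microglia (2.17) and 40 of 41 ribosomal protein genes (1.20), and 19 of 26 homeostatic genes were lower (−0.78), with camera adjusted p of 2.04e-29, 1.13e-23, 2.02e-36 and 3.17e-08, and 0.120, 0.120, 0.120 and 0.127 with an estimated correlation. Adjusted over the list alone these counts were 36, 29, 40 and 20, with 1 disease-associated gene lower and 2 homeostatic genes higher. The class I (median 1.64), inflammatory (1.44), cell cycle (0.97), class II (0.89), lysosomal (0.87), complement (0.68), immediate early (0.63) and oxidative phosphorylation lists (0.37) were higher too, with adjusted p from 0.120 to 0.577 with an estimated correlation. The unfolded protein list (0.32, adjusted p = 0.0158, and 0.656 with an estimated correlation) lost its call without CK replicate 2 or GENUS replicate 4 (adjusted p up to 0.127). The p53 and neuronal marker lists were not called here (adjusted p = 0.0885 and 0.0504). Of the genes called in untreated CK-p25 microglia, 1463 higher and 897 lower ones were also called here, where independent lists would share 289.9 and 151. The correlation of the log2 changes was 0.94, against 0.49 in simulated unchanged groups and 0.84 with the controls split, and the covariance 0.476 against 0.0324.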

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

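The tests of explanations and the counts of other splits in this part were chosen only after the results were seen. The rise of 14 cell cycle genes in CK-p25 neurons was seen in every library, with a median over these genes of 0.540 to 1.12 FPKM in CK, 4.09 to 7.61 in untreated and 4.35 to 6.18 in GENUS-treated libraries. RNA from microglia, which a NeuN sort should remove, would have to bring 25.4% to 1422% (median 80.6%) of the level in untreated CK-p25 microglia. In contrast, 20 microglia markers reached at most 0.116% of theirs, so all 14 genes argue against it. Neuronal nuclei and microglia were sequenced with different kits, so these shares are rough. A larger share of oligodendrocyte precursors could not be judged. Its 5 tested markers had a median log2 change of −0.16 (SD 0.44), against 1.51 for the called genes, which were chosen for their rise. Tnr was at 36.0 FPKM in CK nuclei and Ptprz1, Lhfpl3 and Vcan at 2.76 to 4.05, levels that could hide a small added share. Estimates were above 0 for Cacng4 (0.74, from 0.695 to 1.98 FPKM) and Vcan, and below 0 for Lhfpl3, Tnr and Ptprz1, without a call. A scale of FPKM set by small RNAs would move all genes of a library alike. The 29 measured genes of the list were compared with the median gene of the same library. Their mean log2 level relative to it was 1.02 higher in untreated CK-p25 (−1.22 to −0.85) than in CK libraries (−2.16 to −1.97, exact two-sided permutation p = 0.00794). The libraries already share a median scale, so this restates the rise of the list relative to the median gene and is no separate test of the scale. A larger share of oligodendrocyte precursors, RNA from other dividing cells and a response of the neurons to p25 stay open. Other dividing cells and a response of the neurons were not tested.

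Apoe and Ctsd were the only genes, small RNAs aside, that were listed at 0 in some microglia libraries and stood at 10 FPKM or more in all others. By their highest FPKM they ranked 2 and 3 among all genes, so failed estimates of very abundant genes may account for the zeros, where zeros spread over genes of any abundance would have argued against it. The lowest of these ranks was 3. Ctsb, a related protease, was at 3278 to 4989 FPKM in the same CK-p25 libraries. A real loss of Apoe or Ctsd RNA in single libraries was not tested.

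Astrocyte markers were higher in GENUS-treated than untreated CK-p25 neurons, with a median log2 change of 0.59 that was 0.31 without GENUS replicate 3. Their adjusted p was then 0.0321 with the preset correlation and 0.348 with an estimated one. In that library, out of 4, Apoe was at 156 FPKM against 54.8 to 55.1 in the others. A library with more astrocyte RNA, which the NeuN sort should remove, and an effect of GENUS cannot be told apart, since part of the rise remained and 1 library carried the rest.

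Single libraries far from the others of their group were looked for in 648 groups of values of named genes, and 43 were found. Chance sets a library apart in about 1 in 20 groups. The measure is the gap to the nearest library divided by the range of the group, both on the log2(FPKM + 1) scale. In neurons of CK-p25 mice, GENUS replicate 3 stood apart for Apoe (0.994), C1qb (0.962, 8.11 against at most 1.19 FPKM), Tubb2a (0.935), Psap (0.925), Hsph1 (0.882), Sall1 (0.863), Sparc (0.861, 5.87 against at most 2.11 FPKM) and Snap25 (0.842) as the highest library, and for Snx1 (0.851) as the lowest. Untreated CK-p25 neurons had a highest library for Rpap3 (0.831, replicate 5), Cox6a1 (0.811, replicate 1), Ctsb (0.799, replicate 2), Sall1 (0.726, replicate 3) and Cenph (0.711, replicate 4), and a lowest one for Ppil2 (0.724, replicate 2) and Usb1 (0.723, replicate 4). Mcm3 in CK replicate 3 and C1qb in CK replicate 1 had a ratio of 1, as the other CK libraries were listed at 0.

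In the P301S series the highest library stood apart for Rpl27 (1, wild type replicate 3, the others listed at 0), Sel1l (0.742) and Ctsd (0.717) in GENUS replicate 3, Ift46 (0.716, wild type replicate 2) and Tuba1b (0.639, wild type replicate 6). The lowest did for Cck (0.921, GENUS replicate 1, 92.9 against 144 to 149 FPKM), Dnajb1 (0.732, GENUS replicate 2) and Reln (0.644, untreated replicate 4).

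In microglia, GENUS replicate 4 was the lowest library for Tlr2 (0.912, 333 against 537 to 562 FPKM), H2-K1 (0.899), H2-Q7 (0.892), Cox6a2 (0.862) and Cd14 (0.836), and the highest for Ptger3 (1, 1.14 FPKM with the others listed at 0). Among untreated CK-p25 libraries, replicate 2 was the highest for Ptger3 (1), replicate 3 for Pdia4 (0.872), and replicate 1 the lowest for H2-D1 (0.882). Among CK libraries, replicate 3 was the highest for Cxcl13 (0.904), Bank1 (0.894) and Ptger3 (0.875), replicate 1 the highest for Cfb (0.894) and the lowest for Lpl (0.854), replicate 2 the highest for Rpl13 (0.849) and replicate 4 the lowest for Rps23 (0.830).

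The libraries of each comparison were also split in other ways into groups of the same sizes, up to 100 splits with the real one included. For untreated CK-p25 against CK neurons, only the real split of 100 gave as many as the 127 genes (highest other 11) or the 17 lists (highest other 14). The same held for the 183 genes between GENUS-treated and CK neurons (1 of 100, highest other 5). For the 15 lists of that comparison the share was under 0.05 (3 of 100), and another split gave 16. That split set CK replicates 1, 2, 3 and 5 apart, so it keeps most of the real grouping and cannot show the range of chance. Chance was not excluded for the 8 lists between GENUS-treated and untreated CK-p25 neurons (24 of 100, highest other 15). The split with 15 set untreated replicates 2 to 5 apart, so it too keeps most of the real grouping. Where limma called 0 genes, every split gives as many by construction and the count tests nothing, which held for this comparison (933 genes at an unadjusted p under 0.05, 100 of 100 splits, highest other 2). In P301S against wild type neurons, chance was not excluded for the 1 gene (5 of 100, highest other 1). For the 8 lists the share was under 0.05 (4 of 100), and another split gave 11. That split set wild type replicates 1 and 3 to 6 with untreated replicate 5, so it also keeps most of the real grouping. The shares were not adjusted for the 18 counts tested, and 1 of 100 is the smallest that 100 splits allow. As libraries may not be separate animals, these shares cannot exclude a chance difference between animals. For GENUS-treated against untreated P301S neurons, chance was not excluded for the 3 lists (43 of 100, highest other 7). For GENUS-treated P301S against wild type neurons it was not excluded for the 2 lists (58 of 100, highest other 9). The counts of 0 genes by limma in these comparisons (524 and 701 at an unadjusted p under 0.05) again test nothing (100 of 100 splits each, highest others 1 and 5). The split with 5 genes in the latter, wild type replicates 4 to 6 with GENUS replicates 3 and 4 against the rest, follows the batch read from the values except for GENUS replicate 5, which points to a structure of these libraries, and within each side of the batch 1 gene passed.

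In microglia, only the real split of 35 gave as many as the 2802 genes between untreated CK-p25 and CK (highest other 2). The same held for the 3195 between GENUS-treated and CK (1 of 35, highest other 0). A share of 1 in 35 is the smallest possible here and was not adjusted for the counts tested. Chance was not excluded for the 14 and 13 lists (9 and 16 of 35, highest others 20 and 18). The split with 20 set CK replicate 1 with untreated replicates 1, 3 and 4, and that with 18 set it with GENUS replicates 2 to 4. Both keep much of the real grouping. Between GENUS-treated and untreated microglia chance was not excluded for 4 lists (33 of 35, highest other 13). There the 0 genes by limma (762 at an unadjusted p under 0.05) test nothing (35 of 35, highest other 203). Both highest values came from the split of replicates 1 and 2 against 3 and 4, the batch read from the values, which points to a structure of these libraries. Within the batches 5 and 3 genes passed. That split keeps the numbered pairs together, whereas the real one parts all 4 pairs, and the other 7 splits that part all 4 gave 0 or 1 genes and 3 to 11 lists.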

How the results depend on the processing

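The settings chosen after seeing the data were zeros taken as missing, a mean of at least 5 FPKM, the batch read from the values as a block, each side of that batch alone, and the omission of GENUS replicate 3 with an estimated correlation. Read depth is unknown, so no limit of detection is given, and the cause was not tested for any change below except where fewer genes or libraries entered. Of 85 calls on named genes, 768 of 801 values under other settings kept direction and call and 33 lost the call, in 11 results, and with each library left out 663 of 736 kept it. Of 152 results for named genes that were not called, 1400 of 1412 values stayed so, 9 passed and 3 changed sign. Of 84 called lists, 767 of 790 values kept the call, 695 of 772 with a library left out, and 8 of 84 with an estimated correlation.

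With an estimated correlation, called lists went from 17, 8 and 15 to 3, 0 and 5 in CK-p25 neurons (untreated against CK, GENUS against untreated, GENUS against CK), and to 0 from 8, 3 and 2 in P301S neurons and from 14, 4 and 13 in microglia. With 2 groups in the fit, the counts of genes went from 127 to 71 and from 183 to 85 in CK-p25 neurons, from 1 to 0 for P301S against wild type and from 0 to 1 for GENUS-treated P301S against wild type, where lists went from 2 to 0. A mean of at least 5 FPKM, with fewer genes tested, gave 57 and 109 in place of 127 and 183. Without a filter, GENUS against untreated CK-p25 neurons gave 1 gene and 13 lists, P301S against wild type 2 genes, and GENUS-treated P301S against wild type 1 list. A pseudocount of 0.1 gave 0 genes for P301S against wild type. For GENUS-treated P301S against wild type, 1 gene passed with that pseudocount, without small RNAs and unnamed genes, with zeros as missing, with a mean of at least 5 FPKM, with the batch as a block and on each side of the batch alone. The batch as a block gave 2 genes for P301S against wild type, and 1 list for GENUS-treated P301S against wild type. With fewer libraries, side a gave 5 and 3 genes for P301S against wild type and GENUS against untreated P301S, and side b 4 for the latter. In microglia the sides gave 5 and 3 genes for GENUS against untreated, and side b 1409 and 1740 against CK. The 15 lower genes of untreated CK-p25 neurons became 7 without a filter and 23 without small RNAs and unnamed genes.

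The replicate number as a block gave 72 and 84 genes in place of 127 and 183 in CK-p25 neurons (6 and 15 lower in place of 15 and 48), 1 gene for GENUS against untreated there, 0 genes for P301S against wild type, 7 lists for GENUS against untreated P301S and 1 list for GENUS-treated P301S against wild type. These libraries share only a number. At most 2 libraries of a comparison correlated best with their own number. Between GENUS and untreated microglia, where a pairing by number was not established, the block left 0 genes by limma (762 at an unadjusted p under 0.05 without it) and 4 lists.

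With each library left out, the counts of genes were 77 (without untreated replicate 2) to 149 (without untreated replicate 1) for untreated CK-p25 against CK, 92 (without GENUS replicate 3) to 166 (without CK replicate 5) for GENUS-treated CK-p25 against CK and 0 to 2 for P301S against wild type. Lists were 3 (without GENUS replicate 3) to 13 (without GENUS replicate 2) for GENUS against untreated CK-p25 neurons, 3 to 9 for P301S against wild type, 2 to 7 for GENUS against untreated P301S, 0 to 2 for GENUS-treated P301S against wild type and 4 to 8 for GENUS against untreated microglia. The complement list of CK-p25 neurons gave no value without GENUS replicate 3 or 4, as fewer than 5 members passed the filter. The other libraries that moved a count are named beside each result above.

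The correlation of the p25 and GENUS effects (opposition of GENUS effect to model effect, neurons CK-p25), which would be negative if GENUS ran against p25, was positive at 0.0597 and ranged from 0.0298 without untreated replicate 1 to 0.1002 without untreated replicate 4. By Pearson's correlation, the agreement of model effects, CK-p25 and P301S neurons, was 0.0150 and ranged from −0.00585 without wild type replicate 4 to 0.0504 without wild type replicate 2. The agreement of GENUS effects, CK-p25 and P301S neurons, was −0.0256, 0.0331 without small RNAs and unnamed genes, and ranged from −0.0553 without untreated P301S replicate 6 to 0.00259 without untreated CK-p25 replicate 1.

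Changes of sign among named genes were seen only in genes that were not called. The log2 change of Cdk5r1, neurons CK-p25 GENUS vs NoStim (untreated), was 0.0148 with library weights, 0.0071 with the replicate block and −0.0478 to 0.0574 with each library left out. With each library left out, the log2 change of Mapt, neurons CK-p25 GENUS vs NoStim, was −0.0378 to 0.0258, and the log2 change of Camk2a, neurons CK-p25 GENUS vs NoStim, −0.0351 to 0.0366. The log2 change of Camk2a, neurons P301S NoStim vs WT (wild type), was 0.00146 with library weights and −0.0627 to 0.00166 with each library left out. The log2 change of Mapt, neurons P301S GENUS vs NoStim, was then −0.0427 to 0.0137, and the log2 change of Cdk5r1, neurons P301S GENUS vs NoStim, −0.0270 to 0.127.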

Other observations

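The tests of shared genes and of differences between lists in this part were chosen only after the calls were seen. Neurons and microglia of untreated CK-p25 mice shared some of the genes that rose. Of 8929 genes tested in both cell types, 74 rose in neurons and 1240 in microglia, and 23 rose in both, where independent lists would share 10.3 (Fisher's exact test, odds ratio 2.83, p = 0.000122, across genes, which are not independent replicates). Of 11 and 902 genes that fell, 1 fell in both, where independent lists would share 1.11. Microglia markers that passed the filter were also higher in these neuron libraries (median log2 change 0.84), a call made with the preset correlation and lost with an estimated one. The neuron and microglia libraries also differ in Xist and Ddx3y, as given in the last paragraph of this part.

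List effects were compared between CK-p25 and P301S neurons in 44 tests of the difference, by permutation of the libraries, and 0 passed after adjustment, with 7 at an unadjusted p under 0.05. Interferon genes had a mean log2 change of 0.62 in untreated CK-p25 and 0.02 in untreated P301S neurons against their controls, over 6 members tested in both (difference 0.60, adjusted p = 0.103). Lysosomal genes differed by 0.18 and cell cycle genes by 0.49 (adjusted p = 0.103 and 0.145). For immediate early genes the means were −0.48 and −0.51 (adjusted p = 0.981).

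Xist, expressed from the inactive X chromosome, was at 329 to 412 FPKM in the CK-p25 neuron libraries and Ddx3y, on the Y chromosome, was listed at 0 in all 14. In the 17 P301S neuron libraries Xist was at 0 to 0.136 FPKM and Ddx3y at 8.28 to 14.3, and in the 12 microglia libraries Xist was listed at 0 and Ddx3y was at 16.4 to 23.7 FPKM.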
